A study of Mus musculus with 9 samples.

How the data were processed

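Messenger RNA was measured by RNA-seq in 3 sorted keratinocyte populations from the back skin of mice at postnatal day 60 that carried an inducible Cre recombinase under control of the Tenascin-C gene (Tnc) and a tdTomato reporter. Per the labels' protocols, tamoxifen (100 µg per g body weight) was given on postnatal days 51 and 52, which switches the reporter on in cells that express Tnc at that time. Skin was digested with 0.25% trypsin for 60 min at 37 °C, and cells were sorted on EPCAM, an epithelial surface protein, integrin α6, a basal keratinocyte adhesion protein, SCA1 (encoded by Ly6a), and the reporter. All 3 populations were positive for EPCAM and integrin α6. Touchdome cells were SCA1-positive and reporter-positive, IFE (interfollicular epidermis) cells were SCA1-positive and reporter-negative, and HF (hair follicle) cells were negative for both. Libraries were made from 50 ng of total RNA with poly(A) selection and read as pairs of 150 nt, per the labels' protocols. Each group had 3 libraries, named by the replicate number in their titles. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical in part.

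The deposited table gave, for each library, an expected count and a TPM (length-scaled relative abundance) value for 55357 Ensembl gene identifiers. Per the submitters' processing notes, STAR 2.7.9a, RSEM 1.3.3, DESeq2 1.38.2 and the genome build mm39 were used, and their roles, the annotation release and the strand setting are not given in the sources used here. The expected counts deposited by the authors are estimated counts per gene, not scaled between libraries, and were whole numbers in 92.5% to 94.6% of rows, so reads shared between genes were divided among them and near-identical genes are uncertain. Overlapping and antisense genes are uncertain for the same reason, since the strand setting is unknown. The TPM values deposited by the authors sum to the same total in every library and carry no depth. Gene symbols came from the GENCODE table supplied with the reference, whose build differs from the authors' build, so no coordinates are given. Of the identifiers, 52081 had a symbol. The rest held 0.673% to 2.13% of the counts of a library, of which a single identifier, ENSMUSG00000119584, took 0.513% to 2.01%, highest in IFE replicate 2.

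Expected counts were rounded to whole numbers. Genes were kept by filterByExpr of edgeR 4.0.16 over the 3 groups (minimum count 10, minimum total count 15), which left 15046 genes, and libraries were scaled by TMM factors. Each of the 3 comparisons was tested with the robust quasi-likelihood test of edgeR in R 4.3.3, with the 9 libraries in 1 fit, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Levels are CPM values at the TMM-scaled library size, as mean ± SD over 3 libraries, and fold changes are log2 values ± their standard error (SE). Where a group held 0 counts of a gene, the fold is a lower bound against 3 counts over the group. Where it held 1 to 3 counts, the ratio of summed counts is given with an exact 95% counting interval. Intervals and limits cover counting error only.

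Before the data were examined, 26 gene lists, the rule for naming genes and the alternatives were fixed. Lists with at least 3 tested members (24 lists) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The named genes are the sort genes, all members of the touch dome and Hedgehog lists, and, per comparison, the 6 higher and 6 lower genes with the greatest fold change among those called, with at least 10 CPM in the higher group and no overlap between libraries. They also include up to 4 called members of each list with the smallest p, or 2 members with the highest level where no member passed, the 10 genes by fold for those higher or lower than in both other groups, 6 genes per shared set, and Xist with Y-linked genes. Results for some genes named by this rule are not reported here. The position of Touchdome between IFE and HF was, per gene, its distance from IFE on the log2 CPM scale divided by the distance of HF from IFE. Its median was taken over genes called between HF and IFE with a log2 fold change of at least 1.

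Total counts ranged from 9295059 to 28249763 per library. A count of 0 allows up to 0.114 CPM in the deepest and 0.316 CPM in the shallowest library, at 3 counts of the scaled total. No pair of libraries within a group agreed within sampling noise, since chi-square per degree of freedom was 16.8 to 73.6. The test was run on simulated counts with the real means, dispersions and library sizes, in 3 runs with 200 of 15046 genes changed in simulated Touchdome against IFE. The simulated libraries held no effect shared by libraries of the same replicate number. It recovered 14.0% of genes changed 1.5-fold, 56.7% of those changed 2-fold, 81.3% of those changed 4-fold and 82.7% of those changed 8-fold. Of its 381 calls, 29 were false (7.61%). A simulated position of 0.3 came back as 0.293 to 0.297.

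Replicate numbers are shared between groups. Deviations of same-numbered libraries from their group means correlated over genes at 0.146, 0.173 and 0.203 between Touchdome and IFE, each above the correlation with the other numbers, and each over 0.1. The numbers were therefore taken to pair the samples in that comparison, as an assumption from the data and not from the labels. Deviations within a group sum to 0, so these correlations are not independent of each other, and the pairing was not tested. No pair with HF reached 0.1. The main test has no replicate block, as fixed before the data were examined, and the value with the block is given beside results that it moves. Alternatives were DESeq2 1.42.0 without shrinkage, DESeq2-type size factors, other filters, the 2 groups alone, the replicate block, limma on log2(TPM + 1) and log2(TPM + 0.1), a fold minimum, and each library left out in turn. All columns of the table were used.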

Results

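The data set comprised 9 poly(A) RNA-seq libraries, 3 each from Touchdome, IFE and HF keratinocytes of mouse back skin. Touch domes are small patches of epidermis next to certain hair follicles, where Merkel cells contact sensory nerves. The series asks, by its title, how touch dome keratinocytes that express Tenascin-C relate to the other epidermal lineages. Total expected counts were 10735431 to 15477297 in Touchdome, 14647371 to 28249763 in IFE and 9295059 to 21358479 in HF libraries.

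Tnc (ENSMUSG00000028364), which drives the reporter, stood at 257 ± 48.9 CPM in Touchdome, 4.79 ± 3.22 CPM in IFE and 50.5 ± 8.71 CPM in HF (SD, n = 3 each). Ly6a, which encodes SCA1, stood at 125 ± 18.8 CPM in Touchdome and 153 ± 36.1 CPM in IFE but 1.08 ± 0.753 CPM in HF (adjusted p = 1.1e-06 and 5.16e-07 against HF, edgeR). Itga6, which encodes integrin α6, was lower in HF (422 ± 25.4 CPM) than in Touchdome (886 ± 93.2 CPM) and IFE (1134 ± 249 CPM, adjusted p = 0.000346 and 2.37e-05). Epcam was higher in HF (228 ± 27.5 CPM) than in IFE (122 ± 9.57 CPM, adjusted p = 0.00718, edgeR), with 150.3 ± 55.3 CPM in Touchdome. As gate genes, these values check the labels.

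Over the 15046 genes tested, Touchdome libraries were closer to IFE than to HF. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.934 to 0.968 between Touchdome and IFE libraries, 0.879 to 0.923 between Touchdome and HF, and 0.848 to 0.886 between HF and IFE. Within groups it was 0.958 to 0.979. The first principal component, with 59.2% of the variance, placed IFE at -75.4 to -57.5 and HF at 89.2 to 98.7. Touchdome replicates 1 and 2 lay at -37.6 and -40.7, and Touchdome replicate 3 lay apart from them, nearer to HF, at -2.86.

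Touchdome was first compared with IFE, the population of the same SCA1 gate without the reporter. Krt17, a keratin of follicles and touch domes, was higher in Touchdome by a log2 fold change of 2.60 ± 0.15 (SE, adjusted p = 2.33e-06, edgeR). Gli1, a transcription factor and target of Hedgehog signalling, rose by 5.11 ± 0.37 (adjusted p = 0.000208). Tnc rose by 5.68 ± 0.54 (adjusted p = 0.00322). The small leucine-rich proteoglycan gene Dcn stood at 21.8 ± 4.80 CPM in Touchdome and 0.118 ± 0.172 CPM in IFE. The keratin gene Krt24 stood at 90.0 ± 22.7 and 1.06 ± 0.758 CPM. Kcne4, a potassium channel subunit, had 1 count in the 3 IFE libraries together against 535 in Touchdome, a ratio of 821-fold with a 95% counting interval of 147 to 32479. Pi15 (7.48 ± 0.52) and the protocadherin gene Pcdh20 (5.69 ± 0.44) were also among the genes with the greatest fold changes, and the highest adjusted p of Dcn, Krt24, Kcne4, Pi15 and Pcdh20 was 0.000182. In all, 184 genes were higher and 12 lower in Touchdome than in IFE (edgeR, adjusted p under 0.05), and 170 of the 184 but 2 of the 12 differed at least 2-fold. With the replicate block these counts were 282 and 67. They were 446 and 84 with DESeq2, 102 and 5 with only the 2 groups in the fit, and 105 and 7 without IFE replicate 1.

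The touch dome list (Tnc, Krt17, Cd200 and Gli1) had 4 of 4 tested members higher and 0 lower, with the same count when adjusted over the list alone (camera adjusted p = 4.16e-16, and adjusted p = 0.00627 with an estimated correlation). Tnc is the gene of the reporter and so no independent evidence, and the list was not tested without it. Cd200 rose from 8.69 ± 1.55 CPM in IFE to 24.6 ± 7.96 CPM in Touchdome, and lay at 127 ± 18.1 CPM in HF. The Hedgehog list had 5 of 11 tested members higher and 0 lower (6 and 0 adjusted over the list alone, camera adjusted p = 9e-12, and adjusted p = 0.0389 with an estimated correlation). Its risen members included Gli1, Gli2 (3.60 ± 0.19), the receptor gene Ptch1 (0.97 ± 0.19) and the co-receptor gene Gas1 (0.59 ± 0.11). Ptch1 lost its call in 6 of 16 alternatives, among them leaving out Touchdome replicates 2 or 3 or any IFE replicate. Gas1 lost it without Touchdome replicate 3 or IFE replicate 3. Hhip, another Hedgehog target, stood at 0.360 ± 0.204 CPM in Touchdome and 19.6 ± 2.79 CPM in HF, and did not pass against IFE (adjusted p = 0.0789). Smo, Sufu, Boc, Cdon and Gli3 did not pass, with log2 fold changes of 0.06, 0.11, 0.28, 0.01 and 0.22.

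**Figure D1:**
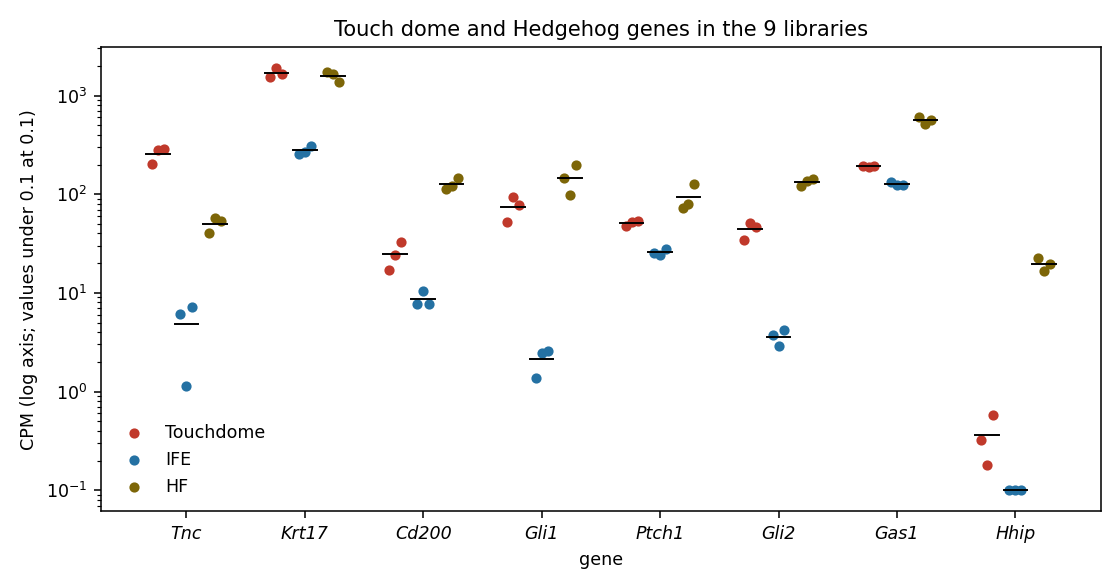
Level in CPM (log axis) of touch dome and Hedgehog genes in each of the 9 libraries, with 1 point per library and a line at the mean of each group. Tnc is highest in Touchdome, Krt17 is at similar levels in Touchdome and HF, and Hhip stays under 1 CPM in the Touchdome and IFE libraries.

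Of the lists of follicle genes, the bulge and hair germ list had 5 of 18 tested members higher and 0 lower (11 and 3 adjusted over the list alone, camera adjusted p = 2.24e-11, but adjusted p = 0.0868 with an estimated correlation). Beside Krt24, they included the transcription factor gene Lhx2 (43.5 ± 29.4 CPM in Touchdome against 5.95 ± 0.822 CPM in IFE, adjusted p = 0.0213) and the growth factor gene Fgf18 (2.67 ± 0.47). The Lhx2 call ended in 6 of 16 alternatives, including without any 1 of the IFE libraries or HF replicate 3. That of Fgf18 ended in 4 of 16, including without IFE replicates 1 or 3. The upper follicle list had 1 of 12 tested members higher and 1 lower (7 and 1 adjusted over the list alone), Krt17 and Lgr6 (camera adjusted p = 0.000193, and adjusted p = 0.313 with an estimated correlation). The hair lineage list had 2 of 14 tested members higher and 0 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.00254, and adjusted p = 0.0826 with an estimated correlation), with Dlx3, a homeobox gene, at 2.41 ± 0.37. The other called member, Lef1, had low levels of 0.575, 0.179 and 1.33 CPM in Touchdome replicates 1, 2 and 3. The sebaceous list had 0 of 13 tested members higher and 0 lower (0 and 0 adjusted over the list alone) and did not pass (camera adjusted p = 0.0814), though it did with the replicate block (adjusted p = 0.0375), and without Touchdome replicate 1 (0.0109), IFE replicate 3 (0.0355) or HF replicate 1 (0.0463).

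The interfollicular differentiation list had 0 of 20 tested members higher and 0 lower (4 and 0 adjusted over the list alone) and passed upward in camera (adjusted p = 0.000127) but not with an estimated correlation (adjusted p = 0.201). Krt10, a keratin of suprabasal cells, stood at 4372 ± 687 CPM in Touchdome and 2974 ± 533 CPM in IFE (adjusted p = 0.200). The basal keratinocyte list had 0 of 14 tested members higher and 0 lower (0 and 1 adjusted over the list alone) and passed downward (camera adjusted p = 0.000152, and adjusted p = 0.313 with an estimated correlation). Krt5 stood at 18930.0 ± 1386 against 23468 ± 1447 CPM and Krt14 at 9868 ± 1593 against 13590.0 ± 1407 CPM. Proliferation genes had 0 of 20 tested members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.677). The immediate early list had 0 of 18 tested members higher and 0 lower (0 and 3 adjusted over the list alone) and passed downward (camera adjusted p = 1.82e-08, and adjusted p = 0.316 with an estimated correlation). The interferon list had 0 of 17 tested members higher and 0 lower (0 and 0 adjusted over the list alone) and passed upward (camera adjusted p = 0.00139, and adjusted p = 0.316 with an estimated correlation). The Wnt list had 2 of 20 tested members higher and 1 lower (7 and 3 adjusted over the list alone) and did not pass (camera adjusted p = 0.0647), though it passed upward without Touchdome replicates 1 or 3 (0.0146 and 0.0128) or IFE replicate 2 (0.0425). The BMP and TGF-beta list had 1 of 22 tested members higher and 0 lower (5 and 1 adjusted over the list alone) and the wound keratin list 0 of 11 tested members higher and 0 lower (0 and 0 adjusted over the list alone). Neither passed (camera adjusted p = 0.131 and 0.626), except without Touchdome replicate 2 (0.0130 and 0.0123). The call of Id2, the BMP and TGF-beta member, ended in 8 of 16 alternatives, including without any 1 IFE or HF library. The Notch list had 0 of 11 tested members higher and 0 lower (0 and 1 adjusted over the list alone) and the nerve guidance list 0 of 21 tested members higher and 1 lower (4 and 2 adjusted over the list alone), and neither passed (camera adjusted p = 0.727 and 0.312). For the proliferation and Notch lists the median and mean fold change were above 0 while camera ranked the list downward. The matrix list had 2 of 23 tested members higher and 0 lower (4 and 0 adjusted over the list alone), with Tnc and Fbln2 called. It passed upward (camera adjusted p = 0.000390, and adjusted p = 0.369 with an estimated correlation), but not without IFE replicate 2 (adjusted p = 0.259). The Fbln2 call ended without IFE replicates 1 or 2, and the list was not tested without Tnc, the gene of the reporter.

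Markers of other cell types moved with the Touchdome group in part. The fibroblast list had 2 of 5 tested members higher and 0 lower (5 and 0 adjusted over the list alone, camera adjusted p = 1.37e-10, and adjusted p = 0.0263 with an estimated correlation). The called members were Dcn and Col1a2, a collagen chain gene that stood at 18.5 ± 3.11 CPM in Touchdome, 0.297 ± 0.349 CPM in IFE and 65.2 ± 9.98 CPM in HF. Col1a1 stood at 2.43, 3.58 and 31.1 CPM in Touchdome replicates 1, 2 and 3. The Merkel cell list had 1 of 5 tested members higher and 0 lower (2 and 0 adjusted over the list alone, camera adjusted p = 0.00486, and adjusted p = 0.0868 with an estimated correlation). The called member, the keratin gene Krt8, stood at 7.16 CPM in Touchdome replicate 1 and 0.804 and 0.996 CPM in the others, and lost its call in 6 of 16 alternatives, including without Touchdome replicate 1 or any 1 IFE library. The Merkel cell transcription factor genes Atoh1 and Sox2 had 0 counts in all 9 libraries, which allows up to 0.192 to 0.268 CPM in the Touchdome libraries. The melanocyte list had 0 of 6 tested members higher and 0 lower (3 and 0 adjusted over the list alone) and the endothelial list 0 of 3 tested members higher and 0 lower (0 and 0 adjusted over the list alone), and both passed upward (camera adjusted p = 0.00525 and 0.0419, and adjusted p = 0.316 and 0.316 with an estimated correlation). The melanocyte call ended without Touchdome replicate 3 (adjusted p = 0.183), and the endothelial call without Touchdome replicates 1 or 3 or any 1 IFE library (adjusted p from 0.0600 to 0.102). The Langerhans cell and T cell lists had no called member, also when adjusted over the list alone, and the Schwann cell list had 0 of 5 tested members higher and 1 lower (1 and 1 adjusted over the list alone). None of these passed (camera adjusted p = 0.312, 0.502 and 0.502), except the Langerhans cell list without HF replicate 3 (0.0430), and the muscle and red blood cell lists had too few tested members. With limma on log2(TPM + 1), the hair lineage, matrix, Merkel cell, melanocyte and endothelial lists did not pass (adjusted p = 0.0666, 0.108, 0.280, 0.108 and 0.0718).

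Of the 12 genes lower in Touchdome than in IFE, Cdh4, a cadherin gene, fell by 1.04 on the log2 scale (adjusted p = 0.00400). Fbxo32 (-0.85), the neurotrophin receptor gene Ngfr (-0.89) and Cpxm2 (-0.75) were lower too. Cdh4 and Fbxo32 lost their calls only with limma on log2(TPM + 1) among 16 alternatives each, whereas Ngfr lost it in 8 and Cpxm2 in 6 of them. For Ngfr these included leaving out Touchdome replicates 1 or 3, IFE replicates 2 or 3 or HF replicates 2 or 3. For Cpxm2 they included Touchdome replicate 1 or any 1 IFE library. The count of 12 was 3 to 29 with 1 library left out, and moved by over 1.5 times without Touchdome replicates 1 or 3, IFE replicates 1, 2 or 3 or HF replicates 2 or 3. Of the 12, 11 were also lower in HF than in IFE. The exception, Lgr6, a stem cell receptor gene of the upper follicle and epidermis, stood at 153 ± 19.6 CPM in Touchdome, 247 ± 36.6 CPM in IFE and 349 ± 21.7 CPM in HF. It was the 1 gene lower in Touchdome than in both other groups (16 genes with the replicate block and 12 with DESeq2, but 0 to 4 with 1 library left out), and its call against IFE ended in 7 of 16 alternatives, among them leaving out Touchdome replicates 1 or 2, IFE replicates 1 or 3, or HF replicate 1.

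Touchdome was next compared with HF. The transglutaminase gene Tgm3 was higher by 6.00 ± 0.30 (adjusted p = 7.89e-08, edgeR), Krt1 by 3.37 ± 0.18 and Krt10 by 2.36 ± 0.18. Bmp3 (7.34 ± 0.42), Apol7a (7.29 ± 0.53), Il20ra (6.39 ± 0.30), Sprr2a1 (6.32 ± 0.92) and Ly6a, a gate gene, led the higher genes beside Dcn. Dcn had 1 count in the HF libraries against 853 in Touchdome, a ratio of 1023-fold with a 95% counting interval of 183 to 40462. The lower genes were led by Aspn (-6.74 ± 0.71), the Wnt receptor gene Fzd9 (-6.66 ± 0.63), Grik1 (-6.46 ± 0.36), Pparg (-6.14 ± 0.86), a regulator of sebaceous and fat cells, Hhip (-5.74 ± 0.44) and Cck (-5.68 ± 0.80). In all, 1773 genes were higher and 1930 lower in Touchdome than in HF, and 918 and 1156 of them by at least 2-fold.

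By list, the bulge and hair germ genes had 0 of 18 tested members higher and 17 lower (1 and 17 adjusted over the list alone) in Touchdome (camera adjusted p = 6.96e-12, but adjusted p = 0.225 with an estimated correlation). Cd34 stood at 47.6 ± 44.4 CPM against 799.8 ± 92.1 CPM in HF and Postn at 861 ± 288 against 3846 ± 483 CPM. Sebaceous genes had 0 of 13 tested members higher and 11 lower (0 and 11 adjusted over the list alone, camera adjusted p = 3.52e-07), and upper follicle genes 0 of 12 tested members higher and 7 lower (0 and 8 adjusted over the list alone, 0.000558). Hedgehog genes had 0 of 11 tested members higher and 8 lower (1 and 8 adjusted over the list alone, 0.000115). With an estimated correlation their adjusted p were 0.225, 0.325 and 0.225. The BMP and TGF-beta list had 3 of 22 tested members higher and 15 lower (3 and 16 adjusted over the list alone, 9.34e-06 with camera, and adjusted p = 0.225 with an estimated correlation), with Bmp4 higher in Touchdome (5.18 ± 0.33) and the antagonist gene Nog lower (-3.66 ± 0.39). Proliferation genes had 15 of 20 tested members higher and 0 lower (16 and 0 adjusted over the list alone, camera adjusted p = 7.9e-11, and adjusted p = 0.225 with an estimated correlation), for example Ccnb2 at 42.0 ± 2.96 against 10.1 ± 0.892 CPM. Interferon genes had 12 of 17 tested members higher and 0 lower (12 and 0 adjusted over the list alone) and differentiation genes 7 of 20 tested members higher and 0 lower (7 and 0 adjusted over the list alone). Both passed (camera adjusted p = 4.2e-07 and 0.00196, and adjusted p = 0.225 and 0.280 with an estimated correlation). The T cell list had 2 of 8 tested members higher and 0 lower (2 and 0 adjusted over the list alone) and passed upward (camera adjusted p = 0.0139, and adjusted p = 0.225 with an estimated correlation); the called members were Thy1 (128 ± 13.3 against 5.71 ± 1.11 CPM), which keratinocytes can also express, and Cd3e, whose call ended without Touchdome replicate 1. The other 13 lists did not pass (camera adjusted p from 0.115 to 0.922). The matrix list had 3 of 23 tested members higher and 10 lower (4 and 12 adjusted over the list alone) and the immediate early list 0 of 18 tested members higher and 3 lower (0 and 1 adjusted over the list alone), and both passed downward (camera adjusted p = 0.0102 and 0.00483, and adjusted p = 0.621 for both with an estimated correlation). Without HF replicate 3 the T cell list did not pass (adjusted p = 0.0893), nor did the immediate early list without Touchdome replicate 2 (adjusted p = 0.0945). The Langerhans cell list passed downward without HF replicate 3 (0.00107) and the melanocyte list without Touchdome replicate 3 (0.0175) or HF replicate 1 (0.0356). The Schwann cell list passed upward with at least 1 CPM in 3 libraries (0.0469).

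The comparison of HF with IFE gives the reference between the 2 reporter-negative populations. The follicle genes Nkd1, Grik1, Gfra2, Strip2 and Sphkap had 1 to 3 counts in the IFE libraries together and 28.1 ± 3.1, 41.0 ± 8.65, 40.9 ± 4.98, 19.9 ± 8.76 and 18.7 ± 2.44 CPM in HF. Crispld1, with 0 counts in IFE, was at least 498-fold higher in HF. Lower in HF were Apol7a (-7.81 ± 0.52), Il20ra (-7.30 ± 0.30), Bmp3 (-6.74 ± 0.42), Il12rb2 (-6.62 ± 0.42) and Mmp3, a matrix metalloproteinase gene at 12.6 ± 7.37 CPM in IFE with 1 count in HF. In total, 2571 genes were higher and 2401 lower in HF, and 1710 and 993 of them by at least 2-fold (edgeR). Of the calls 51.7% were higher in HF, against 71.2% with limma on log2(TPM + 1), where the count of genes lower in HF than IFE was 1209. That scaling moves the median log2 fold change over all genes from 0.00 to 0.19, and that of Touchdome against IFE from 0.00 to 0.13.

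Among lists, bulge and hair germ genes had 16 of 18 tested members higher and 1 lower (16 and 1 adjusted over the list alone) in HF, and sebaceous genes 11 of 13 tested members higher and 0 lower (11 and 0 adjusted over the list alone). Upper follicle genes had 10 of 12 tested members higher and 0 lower (10 and 0 adjusted over the list alone) and Hedgehog genes 9 of 11 tested members higher and 0 lower (9 and 0 adjusted over the list alone). Their camera adjusted p were 5.45e-12, 1.03e-06, 1.57e-05 and 1.3e-07, and 0.143, 0.247, 0.305 and 0.143 as adjusted p with an estimated correlation. The touch dome list had 4 of 4 tested members higher and 0 lower (4 and 0 adjusted over the list alone) in HF as well (1.87e-05 with camera, and adjusted p = 0.143 with an estimated correlation). Proliferation genes had 0 of 20 tested members higher and 17 lower (0 and 18 adjusted over the list alone, 2.84e-09 with camera, and adjusted p = 0.187 with an estimated correlation). The BMP and TGF-beta list had 15 of 22 tested members higher and 5 lower (16 and 5 adjusted over the list alone), the matrix list 14 of 23 tested members higher and 2 lower (14 and 3 adjusted over the list alone) and the melanocyte list 5 of 6 tested members higher and 0 lower (5 and 0 adjusted over the list alone). The interferon list had 0 of 17 tested members higher and 7 lower (0 and 7 adjusted over the list alone) and the basal list 0 of 14 tested members higher and 4 lower (0 and 7 adjusted over the list alone). These 5 passed with camera (adjusted p = 0.000148, 0.000228, 0.0110, 0.000712 and 0.0117) but had adjusted p = 0.305, 0.342, 0.331, 0.324 and 0.370 with an estimated correlation. Of the other 13 lists (camera adjusted p from 0.0908 to 0.947), the Langerhans cell list passed without HF replicate 3 (0.000201) and the T cell list without HF replicates 1 or 2 (0.0438 and 0.0441) or with limma on log2(TPM + 1) (0.0258). The Schwann cell list passed downward with at least 1 CPM in 3 libraries (0.0464). The fibroblast list passed without IFE replicate 3 (0.0486) and the Merkel cell list without Touchdome replicate 1 (0.0460). In both comparisons with HF, none of the 24 lists passed with an estimated correlation, against 11 each with the preset one. In the comparison of Touchdome with IFE it was 3 of 14, the touch dome, Hedgehog and fibroblast lists. With fry, 8, 15 and 17 lists passed for Touchdome against IFE, Touchdome against HF and HF against IFE.

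Genes higher in Touchdome than in both IFE and HF numbered 28. Beside Tnc, Dcn and Kcne4, the 10 named by fold change were Nptx1, a secreted synaptic protein gene (107 ± 37.3, 11.1 ± 1.54 and 28.0 ± 9.50 CPM in Touchdome, IFE and HF), the axon guidance gene Slit1 (10.1 ± 0.516, 2.03 ± 0.723 and 1.12 ± 0.243 CPM), Csrp2, Gadl1, Endou, the transporter gene Slc16a6 and Calm4. Calm4, an epidermal calcium-binding protein gene, had the highest level after Tnc (172 ± 18.2, 87.7 ± 15.1 and 39.0 ± 4.70 CPM). Csrp2 was higher by 1.90 ± 0.26 than in IFE and by 2.90 ± 0.27 than in HF. Leaving out IFE replicate 1 ended the call against IFE for Gadl1, Endou and Slc16a6. The Gadl1 call also ended without any other 1 of the Touchdome or IFE libraries or HF replicate 3, and that of Slc16a6 without Touchdome replicate 2 or IFE replicate 3. The count was 59 with DESeq2 and 44 with no low-count filter.

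Most genes that were higher in Touchdome than in IFE were also higher in HF than in IFE. This held for 162 of 184 genes (88.0%), and for 11 of the 12 lower genes. Independent lists would share 31.4 and 1.91 genes. In 20 simulations of unchanged groups, all 9 libraries were drawn from the same means, and at most 1 and 0 genes were shared. Such groups give hardly any calls, so this does not show what shared IFE libraries give when groups differ. The 22 genes not called higher in HF were all among the 28 genes higher in Touchdome than in HF. Against HF, 114 of the 184 genes were lower in Touchdome and 42 were not called. Of the shared genes, Gfra2 had 3.74 ± 0.570 CPM in Touchdome, Nkd1 2.81 ± 1.54 CPM, Crispld1 2.98 ± 1.03 CPM, Il31ra 15.7 ± 12.9 CPM against 320.4 ± 39.4 CPM in HF, and Angptl7 6.36 ± 3.68 against 166 ± 27.9 CPM. The calls of Il31ra, Angptl7 and Sphkap in Touchdome ended without any 1 IFE library, those of the first pair also without HF replicate 1, and that of Il31ra without HF replicates 2 or 3. The shared count was 245 higher and 49 lower with the replicate block, 388 and 66 with DESeq2, and 91 and 7 without IFE replicate 1. The 11 shared lower genes moved by over 1.5 times without Touchdome replicates 1 or 3, IFE replicates 1, 2 or 3 or HF replicates 2 or 3, to between 3 and 25.

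Conversely, 1577 genes were higher and 1733 lower in both Touchdome and IFE than in HF, where independent lists would share 282.9 and 329.8. Simulated unchanged groups shared at most 1 and 0, again with hardly any calls to share. The named shared ones were Mmp3, Apol7a, Il20ra, Ly6a, Bmp3 and Il12rb2. None of these 6 was called between Touchdome and IFE. Across genes, which are not independent, the fold changes of Touchdome and HF against IFE correlated at r = 0.648, against a mean of 0.490 for simulated unchanged groups. Their covariance was 0.782, against 0.0975 simulated. For Touchdome and IFE against HF, r was 0.858 against 0.499, and the covariance 1.53 against 0.0999. With 3 libraries per group the shared libraries could not be split so that each part kept 2, and part of the excess may come from them.

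**Figure D2:**
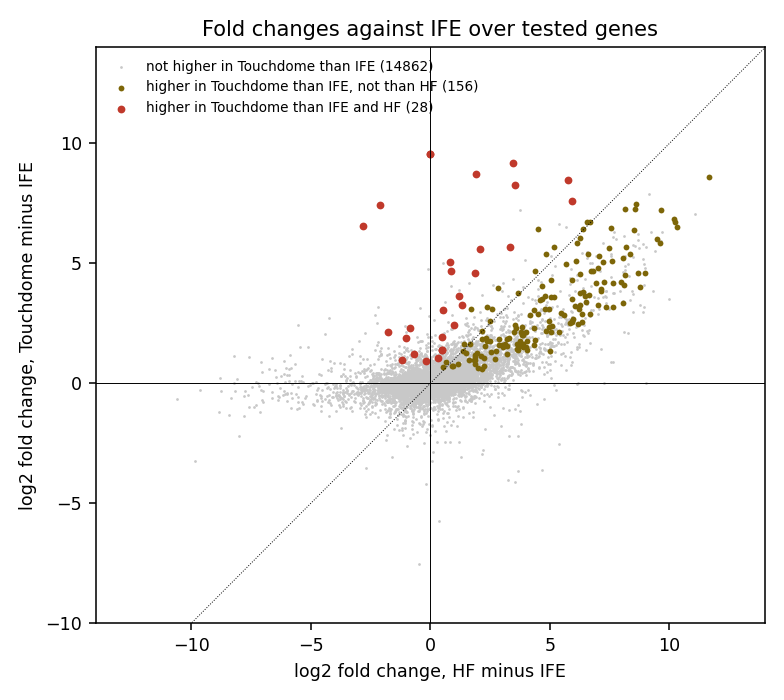
Log2 fold change against IFE of each of the 15046 tested genes, with HF on the horizontal and Touchdome on the vertical axis, and a dotted line of equal values. The 28 genes higher in Touchdome than in both groups lie above the line, and most of the 156 other genes higher in Touchdome than in IFE lie below it on the side higher in HF.

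The position of Touchdome between IFE (0) and HF (1) was nearer to IFE on both sides. Over 1710 genes higher in HF, the median position was 0.286, and the 3 libraries had 0.215, 0.200 and 0.470 (mean 0.295 ± 0.152 SD, n = 3). Over 993 genes higher in IFE it was 0.101, and the libraries had 0.050, 0.0638 and 0.195 (mean 0.103 ± 0.0798 SD, n = 3). When 1 IFE and 1 HF library of the same number were left out and placed by the rest, the IFE libraries had -0.0133 to 0.125 on the first side and the HF libraries 0.962 to 1.02. Touchdome replicate 3 had the highest value on both sides, and without it the medians were 0.190 and 0.0640. On log2(TPM + 1) the second median was 0.0301. No test was applied to these values.

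**Figure D3:**
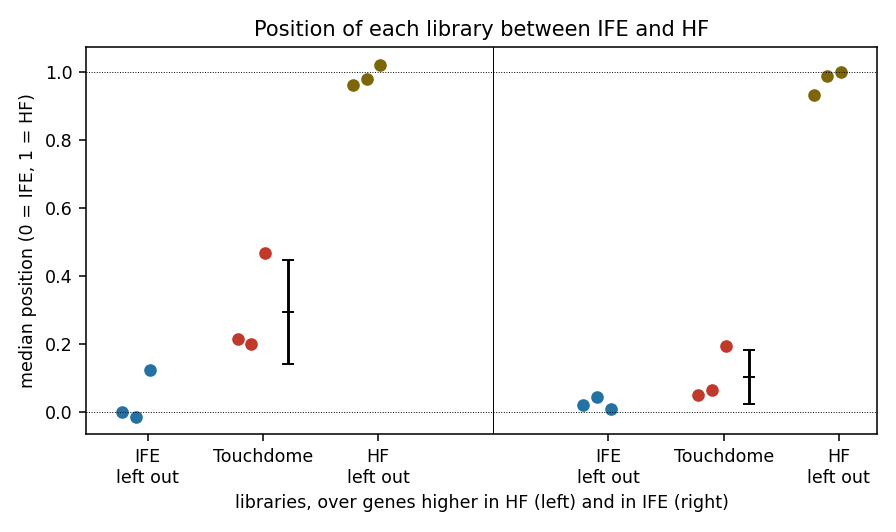
Median position of each library between IFE (0) and HF (1), over genes higher in HF (left) and genes higher in IFE (right), with each point 1 library and the bar the mean ± SD of the 3 Touchdome libraries. IFE and HF points are libraries left out of the axis that places them, and Touchdome replicate 3 is the highest of its group on both sides.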

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

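The replicate block fit with the Touchdome and IFE libraries alone was chosen after the data were seen. No call of a named gene and no list that passed the main test reversed its direction. Of the lists that did not pass, the proliferation, Notch, nerve guidance and wound keratin lists in Touchdome versus IFE, the Wnt, Notch and Langerhans cell lists in Touchdome versus HF, and the Wnt, Notch, immediate early, Langerhans cell and endothelial lists in HF versus IFE had the opposite direction in at least 1 alternative, fry among them, and passed in none of these. The position medians moved by less than the SD between Touchdome libraries, from 0.234 to 0.326 over genes higher in HF and from 0.0301 to 0.109 over genes higher in IFE (0.190 to 0.340 and 0.0640 to 0.12 with 1 library left out). Named gene calls were kept in 551 and lost in 121 checks for Touchdome versus IFE, in 1451 and 53 for Touchdome versus HF, and in 1478 and 56 for HF versus IFE.

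With DESeq2, 446 genes were higher and 84 lower in Touchdome than in IFE, 59 higher and 12 lower than in both other groups, and 388 higher and 66 lower in both Touchdome and HF than in IFE. The 446 and 84 hold all 196 edgeR calls. With no low-count filter, 49 were lower in Touchdome than in IFE, 44 higher and 6 lower than in both, and 41 lower in Touchdome and HF. With only the 2 groups, a fit with fewer samples, the counts were 102 higher and 5 lower than in IFE, 0 lower than in both, and 77 higher and 5 lower in Touchdome and HF. With the replicate block they were 282 and 67, 16 lower than in both, and 245 and 49, and 391 and 145 with Touchdome and IFE libraries alone. The block calls held 195 of the 196 calls for Touchdome versus IFE, 3629 of 3703 for Touchdome versus HF and 4876 of 4972 for HF versus IFE, with 349, 4029 and 5258 calls in all. Of the list calls it changed that of the sebaceous list.

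With limma on log2(TPM + 1), 100 genes were higher and 0 lower in Touchdome than in IFE (164 lower at an unadjusted p under 0.05), the count of genes lower in HF than IFE was 1209, 0 were lower in Touchdome than in both, 74 higher and 0 lower in Touchdome and HF than in IFE, and 981 higher in Touchdome and IFE than in HF. On that scale 9 lists passed for Touchdome versus IFE. With log2(TPM + 0.1), 0 were lower in Touchdome than in IFE (159 unadjusted), 1219 lower in HF than in IFE, 0 lower in Touchdome than in both and 0 lower in Touchdome and HF than in IFE, and 992 higher in Touchdome and IFE than in HF. A fold minimum of 1 on the log2 scale left 2 lower in Touchdome than in IFE, 918 higher and 1156 lower than in HF, 1710 higher and 993 lower in HF than in IFE, 0 lower in Touchdome than in both, 2 lower in Touchdome and HF, and 768 higher and 1079 lower in Touchdome and IFE, which follows from the stricter rule. An estimated correlation left 3, 0 and 0 lists for Touchdome versus IFE, Touchdome versus HF and HF versus IFE, and fry gave 8, 15 and 17. With fry, the Wnt list passed for Touchdome versus IFE, and the interfollicular differentiation, basal, immediate early, interferon, matrix, melanocyte and endothelial lists did not. For Touchdome versus HF the fibroblast, basal and Schwann cell lists passed upward with fry, and the immediate early list did not pass. The Merkel cell and touch dome lists passed downward, as lower in Touchdome than in HF (fry adjusted p = 0.0167 and 0.0384). For HF versus IFE the fibroblast, hair lineage and Merkel cell lists also passed upward, and the interfollicular differentiation, Schwann cell and T cell lists downward. Apart from the fold minimum and the fits with fewer samples, the cause was not tested.

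With 1 library left out, the ranges were 105 to 213 higher and 3 to 29 lower in Touchdome than in IFE, 1396 to 2116 and 1337 to 2242 against HF, 2176 to 2609 and 1887 to 2347 for HF against IFE, 19 to 29 and 0 to 4 against both, 91 to 197 and 3 to 25 in Touchdome and HF, 1257 to 1726 and 1262 to 1841 in Touchdome and IFE, and 13 to 16, 10 to 12 and 11 to 12 lists. The counts 105 and 91 came without IFE replicate 1. In simulated counts for Touchdome versus IFE, 21 of 150 changes of 1.5-fold and 85 of 150 changes of 2-fold were recovered, so a missing call at this depth does not show that a gene did not change.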

Other observations

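The tests of HF and fibroblast carry-over were chosen after the results were seen, and the counts of other splits were not. Among the 28 genes higher in Touchdome than in both other groups, several outside the naming rule, picked here after their values were seen, are known from neurons or their contacts. Zfp536, a zinc finger gene, and Ildr2 had 0 counts in all IFE and HF libraries and were present in each Touchdome library, at least 116-fold and at least 111-fold higher than in IFE. Cadm3, Lrrtm1, Kcnq3, Fat3 and Dscaml1, genes of neuronal adhesion and excitability, were higher too, with Cadm3 at 2.94, 6.26 and 3.49 CPM in Touchdome and at most 1.05 CPM elsewhere. No enrichment test was run, and the fixed nerve guidance list did not pass against IFE. Xist ranged from 1.48 to 277 CPM among the HF libraries and from 12.7 to 252 CPM in Touchdome, while Y-linked Ddx3y was present in all 9 libraries (23.0 to 78.7 CPM). The mix of sexes thus differed between libraries of HF and of Touchdome, which argues against either of these groups being technical repeats of 1 sample. No such statement is made for IFE. Sex was not part of any fit.

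The first pattern is the partial position of Touchdome over genes higher in HF. Some follicle cells in the Touchdome libraries may account for part of it. The SCA1 and reporter gates would remove cells negative for both, as the HF cells were sorted, but not follicle cells positive for both. From 9 genes of the fixed bulge list with at least 10 CPM and 8-fold more RNA in HF than in IFE, the share of HF RNA that would explain their level was 5.31%, 3.99% and 16.7% in Touchdome replicates 1, 2 and 3. Over all 208 genes this strongly higher in HF (at least 20 CPM) it was 4.08%, 3.86% and 16.6%. By list the share ran from -0.0334% to 14.3%, 2.32% to 10.8% and 9.45% to 43.2% over 7 fixed lists, each a median of only 2 to 9 such genes. The upper ends came from the upper follicle list (2 genes) in replicate 1 and the matrix list (4 genes, Tnc among them) in replicates 2 and 3. Krt24 of the bulge list gave 33.8% to 55.0%. A simulated mixture of IFE with the bulge list shares gave median positions of 0.158, 0.129 and 0.347, each below the observed one, by 0.0574, 0.0701 and 0.122 (at most 0.0957 over genes higher in IFE). Left-out IFE libraries strayed by 0.125 in IFE replicate 3 but by at most 0.0133 in the other 2 (at most 0.0452 over genes higher in IFE), so the bound rests on 1 library, and carry-over and expression of follicle genes by Touchdome cells themselves cannot be told apart.

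The second pattern is the set of 162 genes higher in both Touchdome and HF than in IFE. Carry-over with the mean HF profile falls short for 43 of them, which in each of the 3 Touchdome libraries exceeded a mixture with the highest share that any of the 7 lists gives that library, taken at each gene's highest IFE and highest HF library. In 5 mixtures simulated with these shares, 9 to 15 of 251 to 279 called genes did so, so the excess holds for the set and not for each gene. With the lower bulge list shares, 5 mixtures gave 36 to 59 such shared genes, so the 162 observed lie between the 2 settings. The highest share in Touchdome replicates 2 and 3 came from the matrix list, whose 4 genes included Tnc and Fbln2. Both are among the 162 genes and above the bound. The next highest list shares in these replicates were 5.08% and 27.6%. Without the matrix list the bound would be lower there, and the split into 43 and 119 was not repeated. The 43 would need a median of 78.9%, 91.9% and 85.8% HF RNA in Touchdome replicates 1, 2 and 3. They were picked for exceeding the bound, so this share is no further evidence. They include Krt24, Pcdh20 and Krt17, the last at 1693 ± 179.5 CPM in Touchdome and 1584 ± 185 CPM in HF. Tnc, the gene of the reporter, Nptx1 and Kcne4 (0.242 CPM in HF) are also among them. These belong to the 6 of the 162 genes called higher in Touchdome than in HF, which no mixture of the mean levels can reach. The other 119 would need a median of 11.4%, 12.3% and 24.9% and include Gli1 (34.5%, 63.9% and 51.8%), Gli2, Ptch1, Gas1 and Pi15. With this bound, carry-over and expression by the Touchdome cells cannot be told apart for the 119, because at least 1 library lies within it. Gli1, Gli2, Ptch1 and Pi15 exceeded the bound in Touchdome replicates 1 and 2 and lay within it only in replicate 3. There the matrix list, which includes Tnc, set the bound, so for these genes the open reading rests on that list's share. Gas1 lay within the bound in replicates 1 and 3. Carry-over of a follicle subset unlike the HF libraries was not tested.

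The third pattern is the higher level of fibroblast genes in Touchdome than in IFE. RNA from 1 fibroblast source may be suspected, although the EPCAM gate would remove fibroblasts, and the ratio of Col3a1 to Dcn counts stood at 0.105, 0.0565 and 1.20 in replicates 1, 2 and 3, a 21.3-fold range. The exact 95% interval of the last, 0.992 to 1.46, does not overlap the others, but it holds counting error alone, and a spread between 3 separate samples set against it excludes no source. The list is not specific here, since 3 of its 5 tested members were also higher in HF than in IFE, but Dcn stood at 23.8, 25.3 and 16.4 CPM and was nearly absent from IFE and HF, whereas Col3a1 was mostly in replicate 3 (19.7 CPM). One source, several sources and expression of Dcn by touch dome cells cannot be told apart, because no value here measures how far these ratios vary between samples of 1 source.

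Whether other groupings of the libraries give results as large was counted. For each comparison of 2 groups, only 10 splits of the 6 libraries exist, which is too few for a share under 0.05. The real splits called 196, 3703 and 4972 genes for Touchdome against IFE, Touchdome against HF and HF against IFE, and the highest other split called 0 in each. Every other split mixed the 2 groups, which puts their difference into the spread, so it could hardly call genes. For Touchdome against IFE, 4 splits part all 3 same-numbered pairs, and both these and the splits that keep pairs together called 0 genes apart from the real one. Fixed lists past the threshold were 14, 11 and 11, and the highest other splits gave 13, 11 and 11, with 1, 2 and 2 splits reaching the real count. Of 100 drawn assignments of the 9 libraries, the real one included, 1 gave 28 or more genes higher in Touchdome than in both (highest other 0), 1 gave 162 or more genes higher in Touchdome and HF (highest other 5), 1 gave 11 or more lower in both (highest other 0), and 2 gave at least 1 gene lower in Touchdome than in both (highest other 4). For genes higher in Touchdome and IFE than in HF, 2 reached 1577 (highest other 1621), and for genes lower in both, 1 reached 1733 (highest other 1602). Of the 99 other draws, 97 broke up the HF libraries. The 2 that kept them together mixed Touchdome with IFE and gave 1621 and 1602, and 1521 and 1544, for this last pair of counts, and 0 where the real counts were 28, 162 and 11. The shares are under 0.05, but nearly all rest on draws that broke up HF and so could hardly give such counts. The draws therefore do not exclude a chance parting of Touchdome from IFE in any of these 6 counts. With HF kept together only 10 splits exist, each with 2 ways to label its parts, still too few for a share under 0.05.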
